A study of Mus musculus with 4 samples.

How the data were processed

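PolyA-enriched RNA of 4 cultures of mouse hippocampal neurons (P0, CD1) was sequenced with the Illumina TruSeq kit, 1 library for each combination of lentivirus (vector or Kdm6b shRNA) and treatment (none or Bic/4AP for 3 h). The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.8b, Cufflinks 2.0.2 and mouse build mm9, without giving the role of each or the annotation used. The deposited tables hold FPKM, as computed by the authors with Cufflinks, for 22878 rows of 22492 gene symbols, with a lower and an upper bound of the FPKM for each row. The bounds cover counting and read assignment within 1 library and not the variation between cultures. Counts and read totals were not used here, since the tables hold none. Relative depth was estimated from the width of the bounds of genes with an FPKM of at least 5. The median distance from a value to its upper bound was 11.6%, 12.0%, 11.3% and 11.7% of the value at FPKM 1 to 5, and 4.26%, 4.44%, 4.18% and 4.30% at 5 and above, in the order vector untreated, vector Bic/4AP, shRNA untreated and shRNA Bic/4AP. The number of rows listed at 0 was 4435, 4467, 4281 and 4268.

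Rows of one symbol were summed. Symbols with a row marked as failed in any library were left out (8, 13, 9 and 19 rows were so marked), and 268 rows per library marked as low in data were kept. Genes for small RNAs, such as snoRNAs and microRNAs, were recognised by symbol and left out because FPKM of transcripts near the fragment length is unstable, so that small RNA genes with other symbols, among them AF357355 and Bc1, stayed in. Those left out took 9.89%, 5.80%, 4.97% and 14.2% of summed FPKM. The remaining 21723 genes had a summed FPKM of 467725, 477022, 468702 and 481447. The start positions in the tables were found to count from 0, since 551 of 562 microRNA genes (98.0%) had an annotated length equal to end minus start, and are given counted from 1. FPKM were used without further scaling.

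The comparisons were Bic/4AP minus untreated in vector and in hairpin cultures, hairpin minus vector untreated and with Bic/4AP, and the difference of the Bic/4AP responses. A gene was compared when its FPKM was at least 1 in at least 1 compared library, and differences were taken in log2(FPKM + 1), that is with a pseudocount of 1. A difference of at least 1 on that scale was called 2-fold. With 1 library per group there was no test and no p-value. Pearson and Spearman correlations of responses and of hairpin effects were taken across genes. Genes higher with Bic/4AP were chosen in both backgrounds, and also in each alone, because a choice on 1 background makes the other look weaker by regression to the mean. The named genes were the 10 largest and 10 smallest differences of each comparison under the size rule, up to 2 largest and 2 smallest members of each list, and 13 genes always given: Kdm6b, Fos, Npas4, Arc, Bdnf, Nptx2, Inhba, Egr2, Nr4a1, Gadd45b, Btg2, Atf3 and Serpinb2. Any other gene named was chosen after its values were seen. The rules, comparisons and 30 gene lists were fixed before the data were examined.

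Each list was described by its median, its members 2-fold apart and the percentile of its median among 10000 random lists drawn from 20 bins of mean level, where at least 5 members were measured. The lists held activity-dependent genes (immediate-early, late effector and survival), cell death regulators, p53 targets, the TGF-beta pathway, H3K27 methylation and demethylase genes, Hox, interferon-stimulated and inflammatory genes, synaptic, potassium channel, maturation and early development genes, cholesterol, heat-shock, ribosomal, oxidative phosphorylation and proliferation genes, and markers of excitatory and inhibitory neurons, astrocytes, microglia, the oligodendrocyte lineage, endothelial and mural cells, fibroblasts, ependyma and choroid plexus, and erythroid cells. Per1, Dcx and Slc4a4 were left out as failed, and Map2, Hmgcs1 and 6 more listed symbols were not among the rows.

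Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or an FPKM of at least 5, median-ratio, upper-quartile or common-sum scaling, small RNA genes kept, non-overlapping bounds required, and the highest row kept instead of the sum. Leaving out loci under 300 bp, genes under an FPKM of 0.01 in a compared library, and genes with a 3′ UTR word described in the closing section were added after the data were seen. For a symbol with more than 1 row, the largest locus was taken. A correlation was taken as moved beyond 0.05 and a count beyond 1.5 times. A list median was taken as moved beyond the half-width of its bootstrap interval over list members (2.5 to 97.5%). These limits were set after the data were seen.

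Words of 7 bases were also searched in annotated 3′ UTRs of at least 50 nt (GENCODE mouse release 21), over 12121 of 12650 genes (95.8%) with an FPKM of at least 1 in all 4 libraries. Differences were first corrected for UTR length and base composition, and 15946 words in at least 100 genes were ranked by the mean difference between genes with and without the word divided by its standard error. This search was begun after the data were seen. An earlier version used an FPKM of at least 5 and length alone, and hand-picked words and words of 6, 8 and 9 bases were also looked at. On simulated data with a noise of 0.0723 (SD) per library, 33.5% of 200 genes planted at 2-fold and 99.5% at 3-fold were called 2-fold. The planted genes had an FPKM of at least 5 in all 4 libraries. The noise was the same for every gene and came from the interquartile range of the difference of responses. No other gene was called, but noise that small fixes this outcome, so the simulation gives no rate of false calls. Of 10 words planted with a shift of -0.1, each in many genes, 10 ranked lowest. That shift and number of genes largely fixed this outcome. The noise was independent between genes, so the simulation gives no rate of false words. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.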

Results

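RNA from cultured hippocampal neurons of newborn CD1 mice, an outbred strain, was measured by RNA sequencing in 4 conditions with 1 library each. The cultures carried either an empty lentiviral vector (vector) or a lentivirus with a short hairpin RNA (shRNA) against Kdm6b, added on day 4 in vitro. On day 11 they were left untreated or received bicuculline at 50 µM (the labels give 50µm, read here as micromolar) and 4-aminopyridine at 2.5 mM for 3 h (Bic/4AP). Bicuculline blocks GABA-A receptors and 4-aminopyridine blocks potassium channels, and together they raise synaptic firing. There were no replicates, so no difference was tested and every value below describes 1 culture per condition. Levels are FPKM, fragment counts divided by transcript length and sequencing depth, from the authors' tables. Differences are in log2(FPKM + 1), a scale that understates differences of weakly expressed genes. Total counts per library were not available in the tables used here. The authors' bounds put the relative depth of the 4 libraries, in the order vector untreated, vector Bic/4AP, shRNA untreated and shRNA Bic/4AP, at 1, 0.932, 1.04 and 0.994. The number of genes with an FPKM of at least 1 was 13019, 12976, 13141 and 13110. Gene positions are in mouse build mm9.

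The target of the hairpin was examined first. Kdm6b, a demethylase of histone H3 lysine 27, lies on chromosome 11 from 69212020 to 69227177. Its FPKM in the vector cultures was 6.74 (authors' bounds 6.44 to 7.04) untreated and 13.1 (12.7 to 13.6) with Bic/4AP. With the hairpin it was 2.73 (2.55 to 2.92) untreated and 4.83 (4.58 to 5.08) with Bic/4AP. The hairpin cultures therefore held 40.6% of the vector level untreated and 36.8% with Bic/4AP. Bic/4AP went with a level 1.95 times as high in vector cultures and 1.77 times as high with the hairpin. Kdm6b with Bic/4AP and the hairpin stayed below its untreated level in vector cultures.

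**Figure D1:**
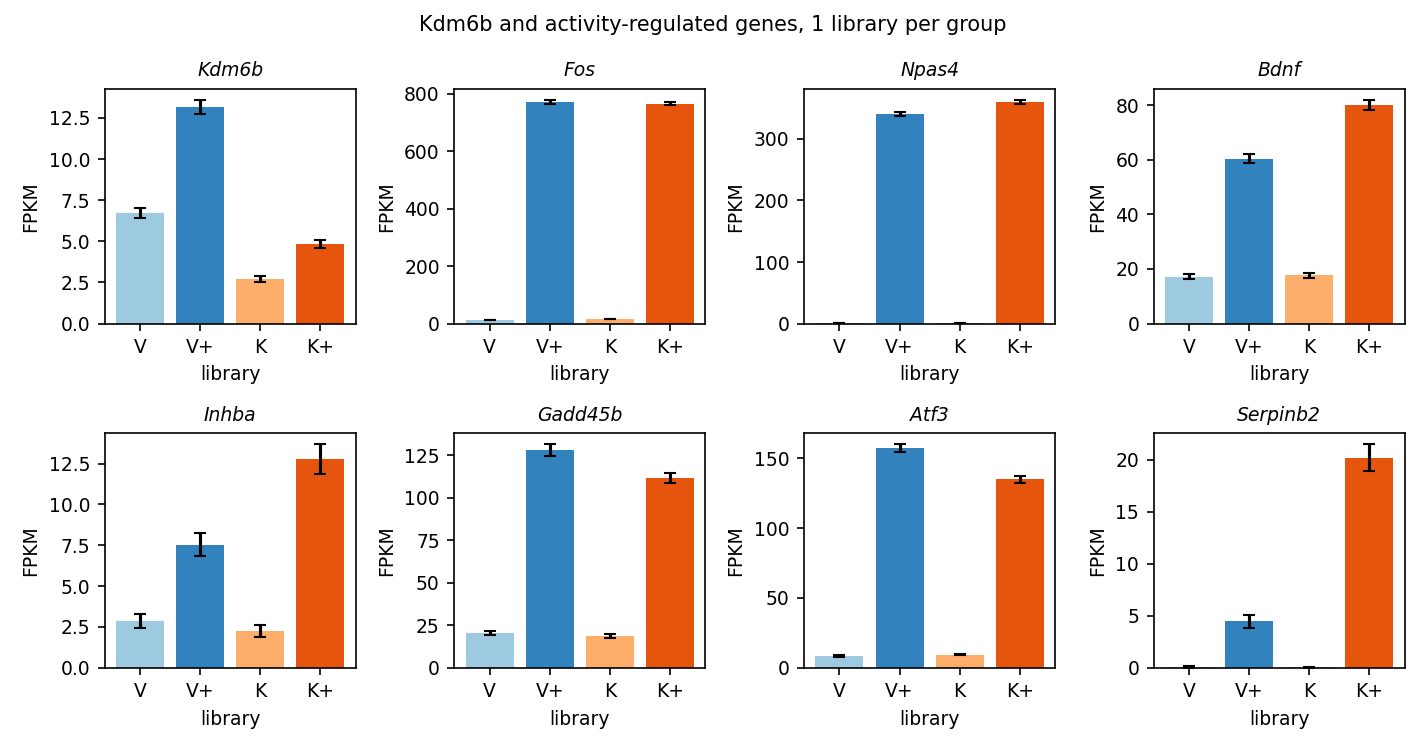
FPKM of 8 genes in the 4 libraries (V vector untreated, V+ vector Bic/4AP, K Kdm6b shRNA untreated, K+ Kdm6b shRNA Bic/4AP), with bars for the level and error bars for the authors' bounds within 1 library. Fos stood at 771 and 765 in the stimulated vector and hairpin cultures, whereas Serpinb2 stood at 4.47 and 20.2.

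The first comparison asked which genes differ after 3 h of synaptic firing in vector cultures. Immediate-early genes held most of the largest differences. Fos stood at 12.5 untreated and 771 with Bic/4AP, Npas4 at 1.52 and 340, and Arc, a regulator of AMPA receptor traffic, at 4.89 and 165. Of 30 late effectors, 26 lay above 0 and 4 below. Among the higher were the neurotrophin gene Bdnf (17.1 and 60.4) and the prostaglandin synthase gene Ptgs2, whose difference was 4.43. Of 13217 genes compared, 294 were at least 2-fold higher and 36 at least 2-fold lower. The lower count depended on the scale, with 394 higher and 130 lower at a pseudocount of 0.1 and 171 and 0 at 5. The 10 largest differences also held Fosb (6.20), Nr4a1 (4.57), Egr4 (4.22) and Klf4 (4.15). A further 2, the snoRNA gene AF357355 and LOC100302567, have loci of 54 and 94 bp and were listed at 0 untreated, so no fold is given. On the lower side stood the G protein-coupled receptor genes Sstr3 (-1.57), Gipr (-1.51), Gpr27 (-1.39) and Oprl1 (-1.26), with Fam123c (-1.51), A930011O12Rik (-1.44), Zkscan16 (-1.35), Cecr6 (-1.26) and Lrrc17 (-1.21). Gm12238, a 124-bp locus, was listed at 0 with Bic/4AP.

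Gene lists fixed in advance were summarised by the median of their members and its percentile among 10000 random lists matched on level. Of 33 measured immediate-early genes, 29 were 2-fold higher, with a median of 2.78 (percentile 100). Klf10 (-0.28) and Srf (0.16) were the smallest members. Of 30 late activity-regulated effector genes, 15 were 2-fold higher (median 1.04, percentile 100), with Penk, the proenkephalin gene, at 2.44 and Lingo1 at -0.68. Of 11 activity-regulated survival genes, 10 were 2-fold higher (median 2.31, percentile 100). The survival list shares 4 genes with the immediate-early list (Atf3, Btg2, Npas4 and Nr4a1) and 3 with the late effectors (Bdnf, Inhba and Serpinb2). Of 22 inflammatory and NF-kB genes, 12 were 2-fold higher (median 1.09, percentile 100), including the chemokine genes Cxcl1 (3.85) and Ccl2 (3.66). Heat-shock and unfolded-protein response genes had a median of 0.57 (percentile 100), with 7 of 20 2-fold higher, led by the chaperone genes Hspa1a (2.31) and Hspa1b (1.96). The p53 target genes had a median of 0.53 (percentile 100), with 4 of 20 2-fold higher, among them Btg2 (2.01) and Plk2 (1.33).

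Genes of the mature neuron lay below their matched lists in the same comparison. Voltage-gated potassium channel genes had a median of -0.42 (percentile 0), with Kcng1 at -1.19 and Kcna2 at -0.85 and 1 of 29 2-fold lower. The 23 neuronal maturation genes had a median of -0.35 (percentile 0) and the 33 synaptic genes -0.32 (percentile 0). Gabrb2, a GABA-A receptor subunit, stood at -0.66, whereas the scaffold gene Homer1 stood at 2.21. Early neuronal development genes had a median of -0.20 (percentile 0.695), although Sox11 (1.10) and Sox4 (0.99) were higher. Among cell death regulators, anti-apoptotic genes had a median of 0.27 (percentile 99.7), with Bag3 (1.60) and Mcl1 (1.05) 2-fold higher of 11 measured. That median was -0.034 when genes had to reach an FPKM of 5. Pro-apoptotic genes had a median of 0.04 (percentile 93.2), with Pmaip1 at 1.17. The TGF-beta, activin and BMP pathway had a median of 0.14 (percentile 99.99), with 3 of 35 genes 2-fold higher, including Bmp2 (1.48). Interferon-stimulated genes had a median of 0.37 (percentile 100), with 2 of 26 2-fold higher, Cxcl10 (3.33) and Gbp2 (1.19).

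Several lists sat near 0. The H3K27 methylation machinery had a median of 0.01 and the other histone lysine demethylases of 0.03, with no member 2-fold apart, and Ezh2, the H3K27 methyltransferase gene, at 0.83. Medians were 0.01 for cytosolic ribosomal protein genes, 0.01 for cholesterol biosynthesis genes and -0.06 for oxidative phosphorylation genes. The sign of the H3K27, ribosomal, cholesterol and oxidative phosphorylation medians differed under at least 1 other scaling. Cell type markers had medians of -0.18 (excitatory neuron), -0.03 (inhibitory neuron), 0.03 (astrocyte), 0.03 (microglia), 0.09 (oligodendrocyte lineage), 0.04 (endothelial and mural), 0.14 (fibroblast and meningeal, percentile 99.0) and 0.15 (ependymal and choroid plexus). The inhibitory neuron and astrocyte signs also differed under other scalings. Proliferation genes had a median of 0.17 (percentile 99.6), with Pcna at 1.76. None of the 39 Hox genes reached an FPKM of 1 in any library. Only 1 erythroid marker of 8 did, Hba-a1, with a difference of -0.77.

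The next comparison asked for the same response with the hairpin present. The immediate-early response was present at similar levels: Fos stood at 15.3 untreated and 765 with Bic/4AP, Npas4 at 1.28 and 360, and Arc at 3.61 and 185. Of 33 immediate-early genes, 29 were 2-fold higher, with a median of 2.60 (percentile 100). Late effectors had a median of 1.26 (percentile 100), with 16 of 30 2-fold higher, and survival genes 2.47 (percentile 100), with 10 of 11. Inhba, the activin subunit gene, stood at 2.23 and 12.8, and Serpinb2, a serpin, at 0.0569 and 20.2. Of 13320 genes, 277 were 2-fold higher and 21 2-fold lower, so that 93.0% of the 2-fold genes were higher. Under scaling to a common sum the counts were 314 and 65, and that share 82.8%. The largest differences outside the genes above were Fosb (6.74), Ptgs2 (5.24), Nr4a1 (4.69), Egr1 (4.18), the chemokine gene Cxcl2 (4.18) and Egr4 (4.11). On the lower side stood Fam123c (-1.46), Cecr6 (-1.35), Larp6 (-1.23), Chst12 (-1.20), Rab40b (-1.17), Sh3bp5 (-1.15), Zkscan16 (-1.13), Sstr3 (-1.13) and Zfp354c (-1.11). Pisd-ps1 was at 7.85 untreated and 0.00172 with Bic/4AP.

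Inflammatory and NF-kB genes had a median of 1.05 (12 of 22 2-fold higher), heat-shock and unfolded-protein response genes 0.55 (6 of 20) and p53 target genes 0.25 (3 of 20), each at percentile 100. Cholesterol biosynthesis genes had a median of 0.25 (percentile 100), with Insig1 at 1.07 and Idi1 at 0.98. Interferon-stimulated genes had a median of -0.30 (percentile 0.01), with Oasl2 at -0.79 and Cxcl10 at 2.28. Medians were -0.22 for potassium channel genes (percentile 1.51), -0.19 for synaptic genes (percentile 0), -0.18 for maturation genes (percentile 0.07) and -0.12 for early development genes (percentile 1.47). Anti-apoptotic genes had a median of 0.11 (percentile 98.9) and pro-apoptotic genes of -0.09. The TGF-beta, activin and BMP median was 0.02 (percentile 99.4), and -0.013 under scaling to a common sum. Medians of the remaining lists were -0.02 (H3K27 machinery), -0.02 (other demethylases), 0.03 (ribosomal), -0.01 (oxidative phosphorylation), -0.11 (excitatory), 0.16 (inhibitory, percentile 99.95), 0.05 (astrocyte), 0.02 (microglia), 0.06 (oligodendrocyte lineage), -0.18 (endothelial and mural), 0.16 (fibroblast and meningeal, percentile 99.97), -0.02 (ependymal and choroid plexus) and -0.01 (proliferation). Of these, the H3K27, demethylase, ribosomal, oxidative phosphorylation, microglia, ependymal and proliferation medians took the other sign under at least 1 other scaling. Hba-a1 stood at -0.06.

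Across 13458 genes, the responses in vector and hairpin cultures, which share no library, had a Pearson r of 0.862 and a Spearman rho of 0.800. Genes are not independent replicates, so no p-value is attached. Both responses held 221 genes 2-fold higher, against 6.05 for independent lists, and 13 genes 2-fold lower, against 0.0562. Of 392 genes 2-fold apart in either response, 381 had the same sign in both.

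**Figure D2:**
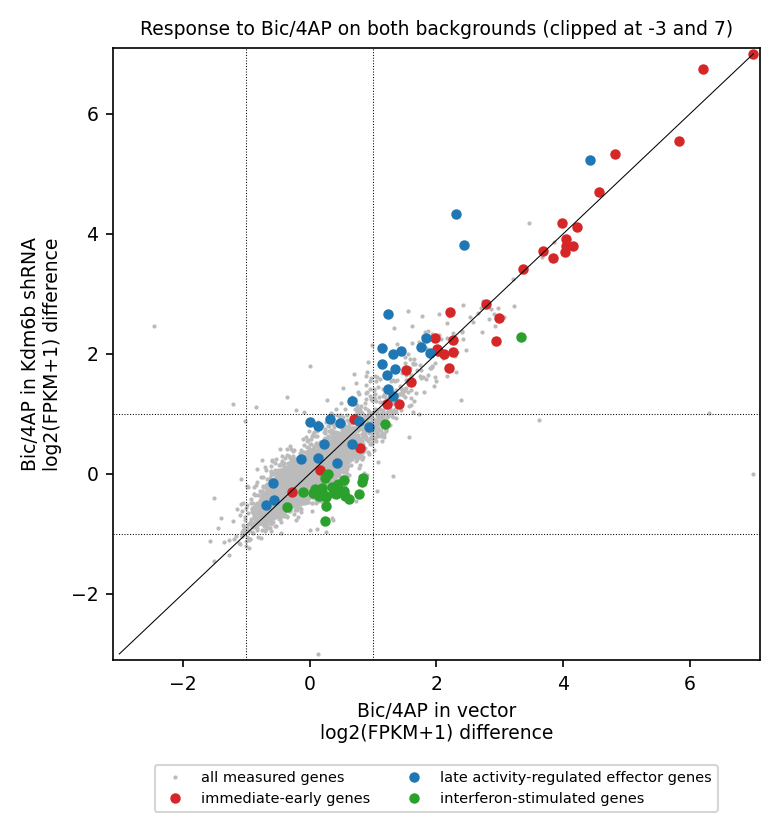
Each point is a gene, with its Bic/4AP minus untreated difference in log2(FPKM + 1) in vector cultures on the x axis and in hairpin cultures on the y axis, clipped to the plotted range. Immediate-early genes (red) and late effectors (blue) extend along the diagonal, with list medians of 2.78 and 1.04 in vector and 2.60 and 1.26 with the hairpin, and interferon-stimulated genes (green) lie below it.

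The next comparison asked which genes differ with the hairpin at rest. Interferon-stimulated genes were higher: 14 of 26 were 2-fold higher and all 26 lay above 0, with a median of 1.06 (percentile 100). Rsad2, which encodes the antiviral protein viperin, stood at 2.01 in vector and 9.004 with the hairpin, Ifi44 at 2.21 and 8.86, and Irf7, an interferon-inducible transcription factor, at 2.21 and 8.55. Microglia markers, measured beside them, had a median of -0.51 (percentile 0), with Tyrobp at -1.46, C1qa at -1.43 and P2ry12 at 0.24. Inhibitory neuron markers were lower, with a median of -0.45 (percentile 0) and 5 of 18 2-fold lower, including the neuropeptide genes Npy (-1.46) and Cck (-1.28). Calb2 was at -0.00 and Vip at 0.11. Late effectors had a median of -0.25 (percentile 0), with 5 of 30 2-fold lower, led by Cort (-1.47) and Npy. Npy and Sst belong to both the inhibitory and the late effector lists. Of 13295 genes, 55 were 2-fold higher and 89 2-fold lower. The excess of lower genes depended on the choices made. As a share it was larger under median-ratio scaling (44 and 99), upper-quartile scaling (45 and 97) and a pseudocount of 5 (11 and 32), and smaller or absent under scaling to a common sum (101 and 117), with a pseudocount of 0.1 (149 and 149), and without genes that have the 3′ UTR word described in the closing section or no annotated 3′ UTR (42 and 39). That word was chosen on these same differences, so the last of these changes was partly fixed by the choice.

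Proliferation genes were higher with the hairpin at rest, with 18 of 19 above 0, 4 of them 2-fold, and a median of 0.57 (percentile 100). Top2a stood at 1.20, Birc5, which is also in the anti-apoptotic list, at 1.18, and Rrm2 at -0.82. Cholesterol biosynthesis genes were lower as a group (median -0.35, percentile 0), with 1 of 20 above 0 and Mvd at -0.70. Medians were -0.23 for potassium channel genes, -0.22 for maturation genes and -0.20 for synaptic genes, each at percentile 0, with Nefh, a neurofilament gene, at -1.03 and Shank3, a postsynaptic scaffold gene, at -0.87. The largest higher genes were LOC100302567 (listed at 0 in vector), Atp6v0c-ps2 (2.50), Ccno (2.003), Gm6320 (1.71), Pbk (1.59), Ckap2l (1.59) and Myb (1.56), beside the interferon-stimulated genes above. Among the lowest were Nptxr (-2.07), the neuronal pentraxin receptor gene, Lyz2 (-1.82), a lysozyme gene of myeloid cells, Scand1 (-1.77), Snap29 (-1.72), Scrt1 (-1.71), Scn3b (-1.70), Araf (-1.69), Ccl6 (-1.62) and Cxcl14 (-1.59). Gm12238 was listed at 0 with the hairpin.

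Immediate-early genes had a median of 0.10 (percentile 91.0) and survival genes 0.02 (percentile 41.1), the latter with the other sign under 2 of 3 scalings. Pro-apoptotic genes had a median of 0.22 (percentile 99.6), with Casp6 at 0.63 and Bid at -0.73, p53 targets 0.20 (percentile 99.8) and anti-apoptotic genes 0.13. No member of the H3K27 machinery (median 0.10) or of the other demethylases (0.09) was 2-fold apart. Medians were 0.08 (TGF-beta, activin and BMP, with Tgfb3 at 1.12), 0.05 (inflammatory), -0.07 (early development, with Stmn2 at -1.34), 0.06 (heat-shock), 0.08 (ribosomal) and 0.03 (oxidative phosphorylation, a sign that differed under other scalings). Other cell type markers had medians of -0.18 (excitatory neuron, percentile 0.28), -0.02 (astrocyte), -0.36 (oligodendrocyte lineage, percentile 0.03, 0 of 11 above 0), -0.19 (endothelial and mural), -0.15 (fibroblast and meningeal, percentile 0.58) and 0.15 (ependymal and choroid plexus). Hba-a1 stood at -0.30.

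With Bic/4AP, the hairpin went with fewer 2-fold differences, 25 genes higher and 71 lower of 13240 (105 and 115 with a pseudocount of 0.1). Microglia markers had a median of -0.85 (percentile 0), with Tyrobp at -1.41, C1qa at -1.32 and Aif1 at 0.04, and 4 of 15 2-fold lower. Interferon-stimulated genes had a median of 0.33 (percentile 100) with 24 of 26 above 0, Ifi44 at 0.97, Rsad2 at 0.82 and none 2-fold higher. Proliferation genes had a median of 0.45 (percentile 100, 16 of 19 above 0), with Cdk1 at 1.13 and Rrm2 at -1.13. Late effectors had a median of 0.18 (percentile 99.97), with Serpinb2 (1.95) and Penk (1.10) 2-fold higher, and inhibitory neuron markers -0.25 (percentile 0), with Cck at -1.20 and Vip at 0.69. Leading genes on the higher side were Lrrc17 (1.93), the small RNA gene Bc1 (1.57, from 2 summed rows), Myb (1.55), Ckap2l (1.46), Gm6320 (1.45), Ccna1 (1.43) and Crip3 (1.24). Amd1 was near 0 in 3 libraries and at 2.49 in the stimulated hairpin culture, and Gm12238 was listed at 0 in the vector culture. On the lower side were 1110001A16Rik (-1.88), Araf (-1.74), Scrt1 (-1.73), E130309F12Rik (-1.72), Lyz2 (-1.59), Ccl6 (-1.57), Scn3b (-1.52) and Cxcl14 (-1.49). AF357355 was listed at 0 and Pisd-ps1 stood at 0.00172 with the hairpin.

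Immediate-early genes had a median of -0.00 (percentile 23.1), survival genes 0.08 (percentile 80.2) and inflammatory genes -0.01 (percentile 16.3) in this comparison. Medians were 0.01 (anti-apoptotic, other sign under all 3 scalings), 0.05 (pro-apoptotic), 0.04 (p53), -0.03 (TGF-beta, activin and BMP), 0.03 (H3K27 machinery, other sign under median-ratio scaling), 0.05 (other demethylases), -0.09 (synaptic, percentile 0.13), -0.10 (potassium channel, percentile 0.535), -0.06 (maturation), -0.05 (early development), 0.02 (cholesterol, other sign under median-ratio scaling), -0.02 (heat-shock), 0.09 (ribosomal) and 0.08 (oxidative phosphorylation). Marker medians were 0.16 (excitatory neuron, percentile 97.52, with Slc17a7 at -0.46), -0.13 (astrocyte, percentile 0.05, with Apoe at -0.72), -0.43 (oligodendrocyte lineage, percentile 0, 1 of 11 above 0), -0.19 (endothelial and mural), -0.17 (fibroblast and meningeal, percentile 0.33) and -0.00 (ependymal and choroid plexus). Hba-a1 stood at 0.42. Across 13458 genes the untreated and stimulated hairpin effects, which share no library, had a Pearson r of 0.723 and a Spearman rho of 0.747. They held 51 genes 2-fold lower in both, against 0.470 for independent lists, and 10 genes 2-fold higher in both, against 0.102.

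**Figure D3:**
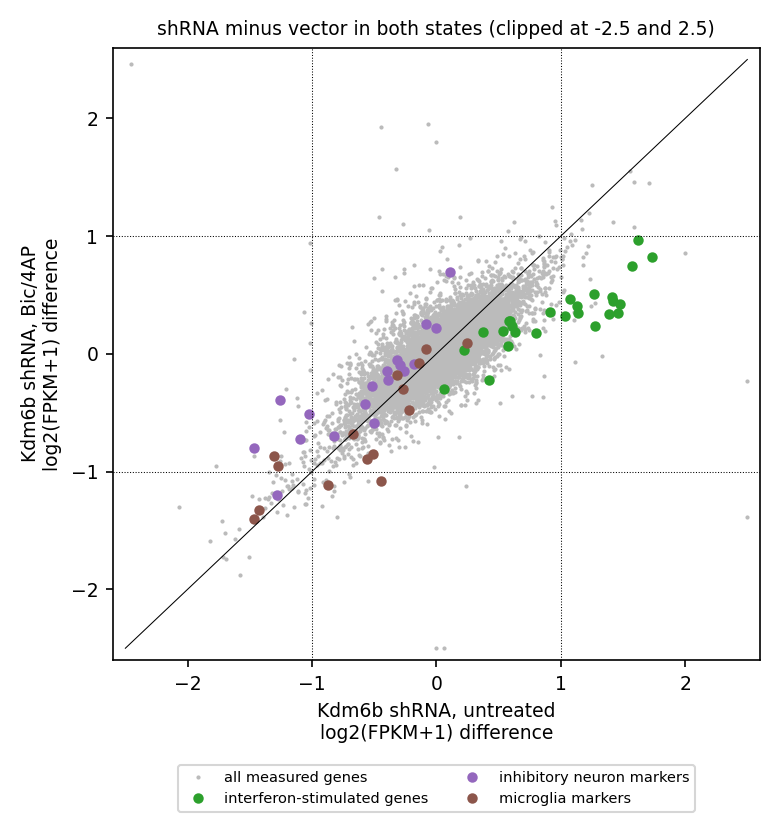
Each point is a gene, with its hairpin minus vector difference in log2(FPKM + 1) untreated on the x axis and with Bic/4AP on the y axis, clipped to the plotted range. Interferon-stimulated genes (green) have medians of 1.06 and 0.33, inhibitory neuron markers (purple) -0.45 and -0.25, and microglia markers (brown) -0.51 and -0.85.

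The last comparison asked whether the Bic/4AP response differed with the hairpin, as the response with the hairpin minus the response in vector. This equals the hairpin effect with Bic/4AP minus the hairpin effect untreated, so a difference at rest enters it as fully as one with Bic/4AP. The 221 genes 2-fold higher in both backgrounds had a median difference of 0.00 (interquartile range -0.17 to 0.23), with 111 above 0 and 110 below. Chosen in vector cultures alone, 294 genes had a median of -0.11, and chosen in hairpin cultures alone, 277 genes had 0.09. The choice in both backgrounds leaves out genes under 2-fold in either, so a response lost on 1 background does not enter it. Chosen on the mean of both responses, which was not planned, 269 genes had a median of -0.01, with 133 above 0 and 136 below. Late effectors had a larger response with the hairpin, with 26 of 30 above 0 and a median of 0.42 (percentile 100). Their median hairpin effect was -0.25 untreated and 0.18 with Bic/4AP, so part of this came from lower levels at rest. Serpinb2 (2.02), Pcsk1 (1.42) and Penk (1.37) were at least 2-fold, Inhba was at 0.95 and Bdnf at 0.35. Pcsk1 stood at 7.67 in vector and 3.14 with the hairpin untreated, and at 19.5 and 25.2 with Bic/4AP. Among survival genes, in the stimulated vector and hairpin cultures, Atf3 stood at 157 and 135, Gadd45b at 128 and 111, Btg2 at 52.5 and 70.4 and Nr4a1 at 124 and 135. The transcription factor gene Egr2 stood at 28.1 and 26.1. Interferon-stimulated genes had the opposite sign, with 0 of 26 above 0 and a median of -0.65 (percentile 0), led by Ifit1 (-1.11) and Cxcl10 (-1.06). Their median hairpin effect was 1.06 untreated and 0.33 with Bic/4AP. Of 13458 genes, 15 were at least 2-fold higher and 17 at least 2-fold lower in the signed difference of responses (39 and 41 with a pseudocount of 0.1). The sign does not give the size of a response. Gipr counts as higher with responses of -1.51 in vector and -0.40 with the hairpin, and Hist1h4k as lower with 0.26 and -0.97. Of the 32 genes, 6 had a locus under 300 bp or an FPKM under 0.01 in a library. Where rows were summed the largest locus was used, so the small RNA gene Bc1 (2 rows, largest locus 346457 bp) was not among them.

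Cholesterol biosynthesis genes lay above 0 in all 20 cases (median 0.33), maturation genes in all 23 (median 0.17), and medians were 0.13 for synaptic, 0.17 for potassium channel, 0.24 for inhibitory neuron and 0.24 for excitatory neuron genes, each at percentile 100. For cholesterol genes the median hairpin effect was -0.35 untreated and 0.02 with Bic/4AP. The p53 targets (-0.14, percentile 0.01), TGF-beta, activin and BMP pathway (-0.13, percentile 0.03), proliferation genes (-0.17, percentile 0.17), anti-apoptotic genes (-0.13, percentile 1.31) and pro-apoptotic genes (-0.10, percentile 1.65) lay at the lower end of their random lists. Immediate-early genes (-0.05, percentile 10.3), survival genes (0.07, percentile 96.8), heat-shock genes (-0.05, percentile 7.44) and the H3K27 machinery (-0.05, percentile 23.0) lay within. Other medians were -0.01 (inflammatory, sign differing under scalings), -0.02 (other demethylases, sign differing under scalings), 0.10 (early development, percentile 98.7), 0.00 (ribosomal, sign differing under scalings), 0.04 (oxidative phosphorylation), 0.04 (astrocyte), -0.01 (microglia), -0.07 (oligodendrocyte lineage), -0.20 (endothelial and mural, percentile 1.85), 0.02 (fibroblast and meningeal) and -0.13 (ependymal and choroid plexus, percentile 1.12). Hba-a1 stood at 0.71. The largest positive differences besides the effectors were those of Lrrc17 (2.37), Pet117 (1.96), Bc1 (1.89), Amd1 (1.804), Snhg9 (1.63) and LOC624853 (1.27). Negative differences included those of Atp6v0c-ps2 (-2.73), 4930562F07Rik (-1.35), Hist1h4k (-1.22), H2-T9 (-1.18), Ccno (-1.14) and Gm5741 (-1.13). Hist1h3i was listed at 0 in the untreated vector culture, and Gm12238, AF357355, LOC100302567 and Pisd-ps1, described above, had the largest differences.

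**Figure D4:**
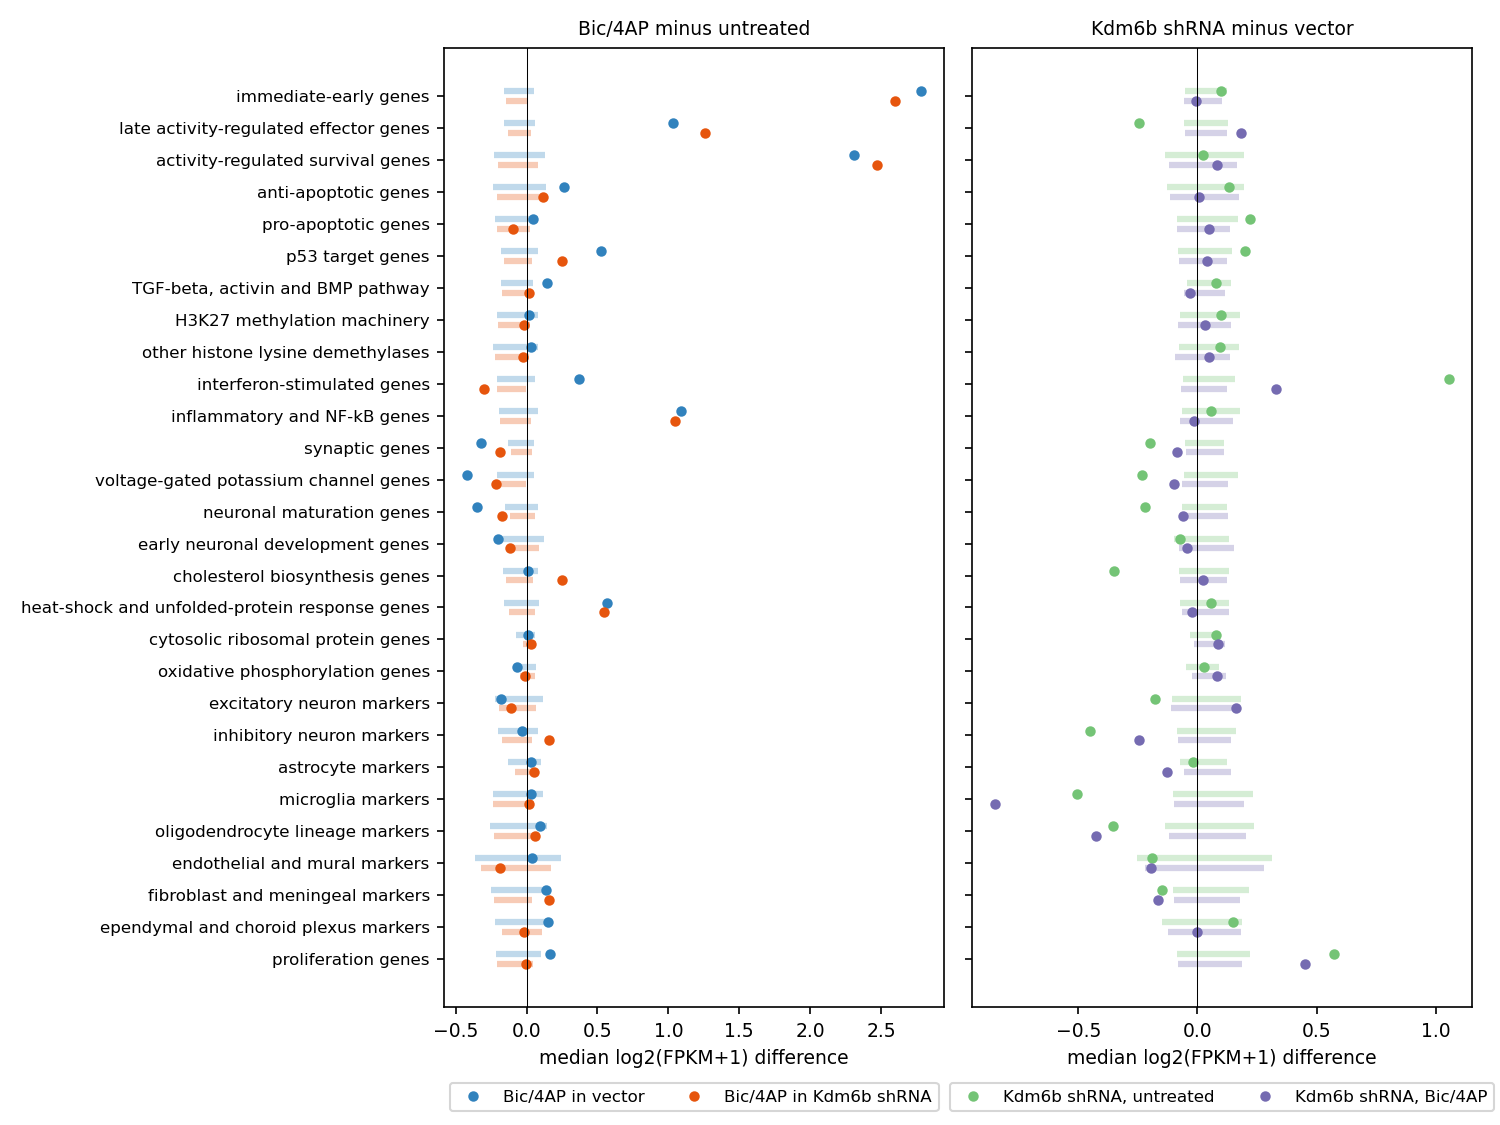
Median difference in log2(FPKM + 1) of each gene list (dots) over the central 95% range of random lists matched on level (pale bars), for Bic/4AP minus untreated on the left and hairpin minus vector on the right. Immediate-early genes have medians of 2.78 and 2.60 on the left, and interferon-stimulated genes have 1.06 and 0.33 on the right.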

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

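The explanations weighed in this part and their tests were chosen after the results were seen, whereas the gene lists and the 3 other scalings used in them were planned. No difference named here was tested for statistical significance, since each condition had 1 library.

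The 51 genes 2-fold lower with the hairpin in both states were rich in a 3′ UTR word. Genes with ACAAGTG, the lowest of 15946 words in the untreated pair of libraries (mean difference -0.131), also ranked lowest in the stimulated pair (-0.133), which shares no library with it, and 23 of the 51 held it and 33 its core ACAAGT, against 17.4 with the core in random lists matched on length, an excess partly fixed by the choice of the word on differences that include these genes. No word of the 21-base hairpin sequence in the labels, of which 18 bases match Kdm6b in a row, came near: the lowest lay at percentile 1.19 of all words (mean difference -0.0199), above a bound of 0.0833, although that bound replaced a looser one of 1.67, under which this explanation had stayed open, after the value was seen. Another small RNA pairing with ACAAGT is a candidate explanation. Whether it was a hairpin other than the labelled one was not tested. The 3 lowest words, ACAAGTG, TACAAGT and CAAGTGA, overlap at positions 5168 to 5176 of the Kdm6b transcript, and the next 2, AACAAGT and ACAAGTA, are absent from it. Of all words, 28.0% occur in that transcript. This share holds for single words and not for 3 that overlap, so these values do not decide the question. Loss of Kdm6b stays open for the 33 genes with ACAAGT and for those without it (18, of which 1 is Kdm6b itself), because no culture had the hairpin and restored Kdm6b. The 18 include the microglia markers C1qa and Tyrobp and the inhibitory neuron marker Cck. For these a smaller share of such cells, weighed below, stays open too. Only the longest annotated 3′ UTR of each gene was searched here, so the 18 may hold ACAAGT elsewhere.

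Interferon-stimulated genes were higher with the hairpin at rest. A larger share of microglia is argued against by the microglia markers, whose median was -0.51, and a scaling difference by a smallest median of 1.005 over the 3 other scalings. A response to the hairpin RNA or to virus dose rather than to loss of Kdm6b cannot be told apart, because no culture carried another hairpin, and the median with Bic/4AP was 0.33.

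Inhibitory neuron and microglia markers were lower with the hairpin, as were oligodendrocyte lineage markers (median -0.36 untreated and -0.43 with Bic/4AP), for which no explanation was tested. A smaller share of inhibitory neurons of all kinds cannot be told apart: 13 of 18 markers had a fold bound above that of Gad1 (fold 0.463) and Calb2 was at 0.999, but the bounds cover 1 library and Gad1 was chosen after its values were seen. A smaller share of microglia stays open for the same reasons, with 7 of 15 markers above the bound of C1qa (fold 0.327), also chosen after its values were seen and among the lowest. ACAAGT sites in the markers' own UTRs are argued against as the whole cause by a pooled median of -0.44 in the 27 markers without the word. A change in some kinds of these cells, or in their expression with less Kdm6b, may remain and was not tested.

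Some results had opposite signs in 2 settings of the same contrast. With the hairpin, the late effector median was -0.25 untreated and 0.18 with Bic/4AP, and the excitatory neuron marker median -0.18 and 0.16. With Bic/4AP, the interferon-stimulated gene median was 0.37 in vector and -0.30 with the hairpin. Gm12238, a locus of 124 bp listed at 0 in the stimulated vector and untreated hairpin cultures, so that its values rest on the pseudocount and give no fold, stood at -2.46 in vector and 2.46 with the hairpin for Bic/4AP, and at -2.46 untreated and 2.46 with Bic/4AP for the hairpin. LOC100302567, a locus of 94 bp listed at 0 in the untreated vector culture, so that its untreated value gives no fold, stood at 3.90 untreated and -1.39 with Bic/4AP for the hairpin. Lrrc17 stood at -1.21 in vector and 1.16 with the hairpin for Bic/4AP.

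Small RNA genes, left out of the comparisons, held values over 1000 FPKM that differed between libraries. FPKM of transcripts near the fragment length is unstable, so the values below are listed and not read as changes. Of 240 measured, 88 were 2-fold higher and 89 2-fold lower in the signed difference of responses. At 0 in a library and at 1000 or more in another were 4 of them. Those named here reached 1000 in a library other than untreated vector and were at least 2-fold above untreated vector there. In the order vector untreated, vector Bic/4AP, hairpin untreated and hairpin Bic/4AP, Snord37 stood at 0, 1473, 2629 and 2071, Snord42b at 442, 474, 1693 and 445, Snord47 at 534, 1375, 307 and 1288, Snord64 at 26142, 0, 0 and 52584, and Snord69 at 448, 1202, 859 and 451.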

How the results depend on the processing

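The 3 alternatives that leave out short loci, near-0 genes, or genes with ACAAGT or no annotated 3′ UTR were chosen after the data were seen. No paired analysis was possible because each condition had 1 library and no label pairs the cultures, and leaving out a replicate could not be done for the same reason. Of 980 list medians under alternatives, 938 stayed within the half-width of their bootstrap interval and 40 moved further. That interval covers the spread between list members and not between libraries. The other 2, in the outer 5% of their random lists, changed sign. Counting medians near 0 as well, 22 of 140 took the other sign under at least 1 scaling, all within 0.0642 of 0 as reported. Of 122 counts, 85 stayed within 1.5 times. Of 28 correlations, 25 stayed within 0.05, and 21 of 21 values for induced genes stayed within their limits. Of 11315 values for named genes 10030 stayed within their limits and 1285 moved, none changing sign among those called. Depth limits genes of low level most, and the bounds do not include variation between cultures.

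Changes with the pseudocount follow from its construction, since a larger one shrinks differences of weakly expressed genes. With 0.1, the genes 2-fold lower with Bic/4AP numbered 130 in vector and 97 with the hairpin. The hairpin then had 149 higher and 149 lower untreated and 105 higher and 115 lower with Bic/4AP, and the difference of responses 39 and 41. For hairpin effects Pearson r was 0.667 and Spearman rho 0.739, and Kdm6b was at -1.27 untreated and -1.43 with Bic/4AP. With 5, the Bic/4AP counts were 171 higher and 0 lower in vector and 160 and 1 with the hairpin. Hairpin counts were 11 and 32 untreated and 4 and 26 with Bic/4AP, and those of the difference of responses 7 and 4. Medians of interferon-stimulated genes were 0.20 and -0.20 for Bic/4AP in vector and with the hairpin, 0.62 and 0.22 for the hairpin untreated and with Bic/4AP, and -0.41 for the difference of responses. Kdm6b was at -0.60 and -0.88.

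Scaling to a common sum multiplies values and so acts like a smaller pseudocount. Genes lower with Bic/4AP numbered 79 in vector and 65 with the hairpin, genes higher with the hairpin 101 untreated and 51 with Bic/4AP, and the difference of responses held 28 and 30. The TGF-beta, activin and BMP median for Bic/4AP with the hairpin was -0.013, a changed sign beside a median of all genes that moved the same way, from -0.08 to -0.12, and Kdm6b was at -1.17 and -1.37. Under median-ratio scaling, 22 genes were lower with Bic/4AP in vector, where the median of all genes moved up from -0.07 to 0.0018. The interferon-stimulated median for Bic/4AP with the hairpin was -0.21, and the median of all genes there moved by a similar amount, from -0.08 to -0.00066.

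Without a filter, Spearman rho was 0.711 for Bic/4AP responses and 0.658 for hairpin effects, whereas Pearson r was 0.849 and 0.705. The cause was not tested. With an FPKM of at least 5, fewer genes were compared: 13 were higher with the hairpin and Bic/4AP, and the anti-apoptotic median for Bic/4AP in vector was -0.034. With small RNA genes kept, more genes were compared. Genes lower with Bic/4AP then numbered 92 in vector and 92 with the hairpin. Hairpin counts were 117 higher and 160 lower untreated and 79 and 133 with Bic/4AP, and those of the difference of responses 103 and 106. Without genes that have ACAAGT or no annotated 3′ UTR, 42 were higher and 39 lower with the hairpin untreated, where lower genes had been in excess, and 15 were higher and 25 lower with Bic/4AP, of fewer genes compared. ACAAGT is the core of a word chosen as the lowest on the untreated hairpin differences. The loss of the excess untreated was therefore partly fixed by that choice.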

Other observations

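The word search described here was chosen after the data were seen. In coding sequences of 12222 genes, ACAAGTG ranked 2 of 16337 words untreated (mean difference -0.0552) and 1 with Bic/4AP (-0.0646). In the Bic/4AP responses it ranked 4642 in vector and 3658 with the hairpin among 3′ UTR words. Genes with 0, 1, 2 and 3 or more copies of ACAAGT numbered 8128, 2705, 858 and 430, with median UTR lengths of 1019.5, 2129, 3103 and 4580 nt. Corrected for UTR length and base composition, their median difference with the hairpin was 0.034, -0.024, -0.049 and -0.065 untreated and 0.035, -0.025, -0.055 and -0.079 with Bic/4AP. ACAAGT is the core of the word that ranked lowest on these untreated differences, so the lower untreated medians with copies were partly fixed by that choice. The genes lower in both states include Becn1, an autophagy gene, which was chosen after its values were seen.

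Nptx2, a neuronal pentraxin gene, stood at 21.1 and 54.2 in vector and 15.7 and 65.9 with the hairpin. Of 57 genes at least 4-fold higher with Bic/4AP in both backgrounds, a choice not planned, the median difference of responses was 0.02. That choice leaves out genes under 4-fold in either background.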
